A study of Homo sapiens with 38 samples.

How the data were processed

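RNA sequencing of polyadenylated transcripts was carried out on 38 samples of 3 established human breast cancer cell lines, T47D, T47D-TR and BT-549, grown with insulin and fetal bovine serum. Per the labels, total RNA was extracted with RNeasy kits and libraries were made with the NEBNext Ultra II system. Cells received MS177 (a degrader directed at the histone methyltransferase EZH2), its negative controls MS177-N1 and MS177-N2, or the EZH2 methyltransferase inhibitor C24, each at 2.5 uM for 48 h, and the vehicle groups received 0.125% DMSO. T47D-TR cells also received MS8815 (a second EZH2 degrader), its negative control MS8815-N or the inhibitor EPZ-6438, each at 2.5 uM for 30 h, with 0.05% DMSO as vehicle. The 19 groups held 2 samples each. The labels do not say whether the replicates of a group were separate cultures, so they may be technical.

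Each of 15 tables deposited by the authors set 1 compound beside the DMSO libraries of its line and time, in 4 columns and 15648 to 18573 genes. Values in every deposited table were on a log2 scale. They were taken as a variance-stabilizing transform of size-factor-scaled counts, computed by the authors within that table. The labels name RSEM and DESeq among the authors' tools without versions, and hg38 as the genome build. The lowest value, a count of 0, lay between 3.45 and 9.28 depending on the table, so differences on the deposited scale were compressed to a different extent in each table and were not compared between tables. Undoing the transform gave normalized counts. Transforming these counts again and undoing it returned them with a largest relative error of 7.94e-15. That checks the arithmetic and not whether the deposited values follow this transform. In the T47D and BT-549 tables these counts were whole multiples of 1 step per library (100% of values up to 1000 reads, within 0.05 of a whole read), which gave the reads of each library over the listed genes: 32.1 to 49.9 M. Each listed gene had at least 10 reads in sum over the libraries of its table. Only 9.4 to 13.0% of values passed that test in the T47D-TR tables, so their depth is unknown. That their values are size-factor-scaled counts is an assumption. Intervals and spreads cover counting error and the spread between the libraries at hand only.

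The second treated column of the T47D MS177-N1 table carries the name of MS177-N2, and its reads equalled those of MS177-N2 replicate 2 at 100% of 17724 shared genes. It was taken as that library, which left MS177-N1 in T47D with 1 library. That comparison used 3 libraries and assumed that the lone library varied as the DMSO libraries did. No replicate of it could be left out and no replicate block could be fitted there.

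The 15 comparisons with DMSO used limma (version 3.58.1, R 4.3.3) with a mean trend and robust empirical Bayes on the deposited log2 values of each table. Genes more than 1 unit above the table's lowest value in at least 2 libraries were tested, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. This filter asks for more counts where the lowest value is higher, so numbers of tested genes are not alike between tables. On the back-transformed scale, with at least 10 normalized counts, MS177 changed 7945 of 14555 genes in T47D-TR and 3924 of 16336 in BT-549. The 11 comparisons between compounds and the 3 comparisons of the MS177 response between lines used the same limma test on log2(normalized count + 1), with at least 10 normalized counts in at least 2 libraries. For these, the tables of a line were brought to 1 scale through the DMSO libraries they share, by 1 factor per table in T47D and BT-549 and gene by gene in T47D-TR. The plan written before the data were examined foresaw the deposited log2 values for these 14 comparisons too. The scale was changed because compression differs between tables, and the planned form was run as an alternative. Comparison of MS177-N2 with the mean of MS177-N1 and C24, and of the MS177-N1 response between lines, was added after the values had been seen, with the same test.

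A set of 23 gene lists of 13 to 100 genes, fixed before the data were examined, was tested with limma's camera (preset correlation 0.01), adjusted over the lists of a comparison. Lists with fewer than 5 tested members were described and not tested. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera takes its degrees of freedom from the libraries (2 or fewer in comparisons with DMSO) and no longer from the number of genes. It can therefore lose calls even where genes are not correlated. Fry asks whether the genes of a list changed in a shared direction and not whether they differ from other genes. Named genes followed a rule written at the same time. EZH2, EZH1, EED, SUZ12, FOXM1 and MYC were always named. Against DMSO, the 6 largest rises and 6 largest falls past the threshold were named for MS177 and MS8815 (3 and 3 for other compounds). These needed both treated libraries outside the DMSO range and a group mean of deposited values at or above the median of the table. Between compounds and between lines, a mean of at least 100 normalized counts was required instead. Up to 4 members of each described list with the smallest adjusted p were named too. Clone names, readthrough genes and pseudogenes were passed over, and some genes that the rule names are not reported here. Gene symbols are those of the tables, and 86.8 to 96.3% of them matched the annotation used for positions, length and GC content.

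The alternatives planned were quantile scaling, no filter on low values, all libraries of a line and time in 1 fit, limma without the mean trend, leaving out each library, the replicate number as a block, and estimated correlations for lists. Added after the data were seen were the back-transformed scale, limma voom on the recovered reads, a pseudocount of 0.5 in place of 1, and fits without 3 doubted libraries. The planned pseudocount alternative for comparisons with DMSO did not apply to log2 values. Quantities were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.

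The tests were checked on simulated data with 200 changed genes, 100 at 2-fold and 100 at 4-fold. Changed genes were drawn from the more abundant ones, and all genes of a group shared the same dispersion. Real genes differ in spread and many have low counts, so recovery in the real data may be lower. With the spread of the DMSO libraries, 100 of 100 genes changed 2-fold were recovered for MS177 in T47D and in BT-549, and 93 of 93 tested ones in T47D-TR. With the spread of the treated libraries (dispersion 0.122 against 0.00152 for DMSO), 0 of 100 were recovered at 2-fold and 0 of 100 at 4-fold for MS177 in T47D. For MS8815 (dispersion 0.0555), 10 of 100 were recovered at 2-fold and 83 of 100 at 4-fold. The list test was checked with the FOXM1 and G2/M list lowered 2-fold and no other gene changed. For MS177 against C24 in T47D-TR, with 5 degrees of freedom, it called that list and 0 of 21 others, also with an estimated correlation (adjusted p = 1.35e-06). For MS177 and MS8815 against DMSO it called that list in every case, and 0 others except 1 of 20 for MS177 in T47D-TR with the spread of the treated libraries. With an estimated correlation, that list reached adjusted p = 0.0079 to 0.0151 with the spread of the DMSO libraries. With the spread of the treated libraries it was missed for MS177 in T47D (adjusted p = 0.192) and for MS8815 (adjusted p = 0.0778), although its genes had been simulated as independent. For that reason these runs cannot show whether the preset correlation gives false calls of correlated lists. For MS177 against MS177-N1 in T47D, estimated correlations were 0.383 for mitochondrially encoded transcripts and 0.029 for FOXM1 and G2/M genes.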

Results

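Transcript levels were measured in 38 samples of the breast cancer cell lines BT-549, T47D and T47D-TR, 30 after 48 h and 8 after 30 h, with 2 samples in each of 19 groups by the labels. The tables held 1 library of MS177-N1 in T47D. The series addresses how EZH2 degraders act on EZH2, the transcription factor FOXM1 and growth. EZH2 is the catalytic subunit of polycomb repressive complex 2, which methylates histone H3, and FOXM1 drives genes of mitosis. Libraries of T47D and BT-549 held 32.1 to 49.9 M reads over the listed genes, and the depth of the T47D-TR libraries is unknown. Levels are normalized counts (mean ± SD, n = 2 per group unless stated), folds are ratios of these means, and log2 differences against DMSO are on the deposited, compressed scale (± SE). Each compound was first compared with DMSO to ask which transcripts it changes.

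**Figure D1:**
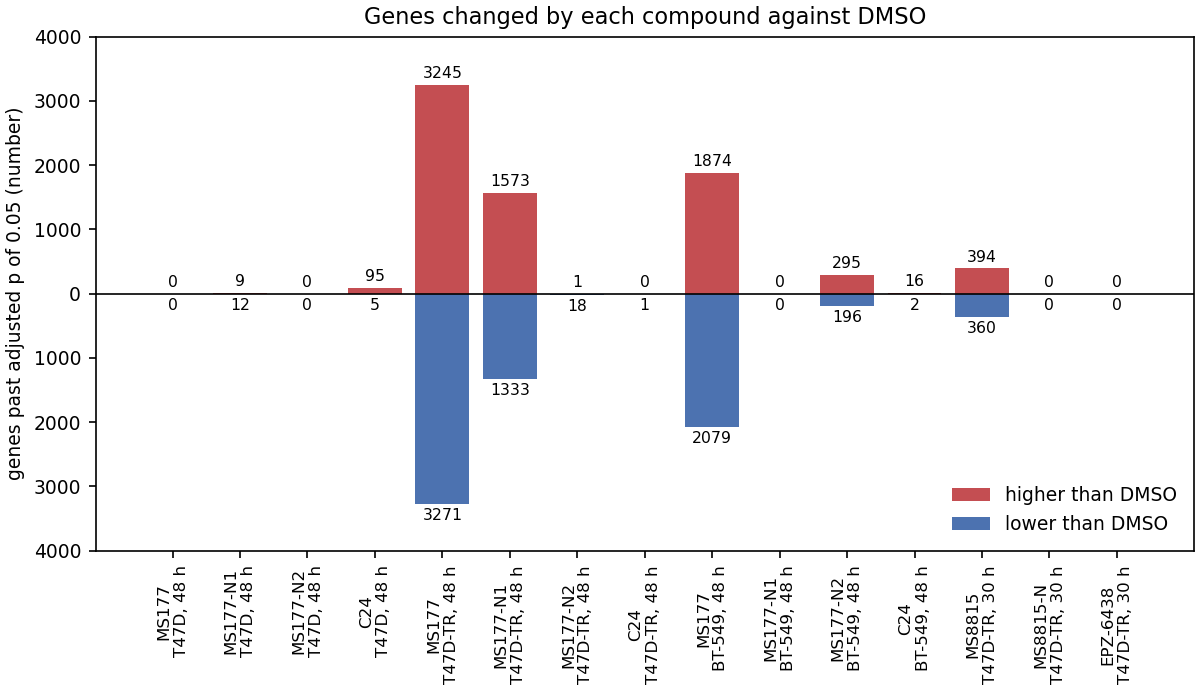
Genes past an adjusted p of 0.05 (limma) for each compound against the DMSO of its line and time; bars above 0 count genes higher than DMSO and bars below 0 count genes lower. MS177 gave 3245 higher and 3271 lower genes in T47D-TR, and 1874 and 2079 in BT-549, while MS177-N1 in T47D-TR gave 1573 and 1333. The filter follows the lowest value of each table, so the tested genes differ between bars.

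With MS177 in T47D-TR, FOXM1 (hg38 chromosome 12, 2857681 to 2877155) fell from 1459 ± 189 to 232.6 ± 1.601 normalized counts, 6.27-fold, a log2 difference of -1.68 ± 0.10 (limma adjusted p = 2.17e-05). EZH2 itself (chromosome 7, 148807383 to 148884321) rose from 247 ± 10.8 to 359 ± 19.6, 1.45-fold (adjusted p = 0.0172, limma). SUZ12, a partner of EZH2 in the complex, fell from 1793 ± 59.2 to 1204 ± 8.42 (adjusted p = 0.00292, limma), and the growth regulator MYC rose 1.31-fold (adjusted p = 0.0253, limma). EZH1 was 272 ± 80.1 in DMSO and 280 ± 19.5 with MS177 (adjusted p = 0.819, limma), and EED lay below the filter.

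AREG, a ligand of the EGF receptor, showed the largest rise on the deposited scale in T47D-TR, from 134 ± 19.1 to 8987 ± 1258. DDIT3, a transcription factor of the stress response, rose from 313 ± 10.9 to 8508 ± 716. SAT1, which breaks down polyamines, rose from 708 ± 130 to 13780 ± 2690. GDF15, a stress-induced cytokine, rose 34.2-fold, ATF3 23.8-fold and INHBE from 7.08 ± 0.63 to 2511 ± 65.5. Limma adjusted p for these rises lay at 4.6e-06, and at 8.46e-06 for SAT1. The largest falls on the deposited scale were those of IGFBP5, which binds insulin-like growth factors (42790 ± 6227 to 1611 ± 100.9, adjusted p = 5.14e-06, limma), and RRM2, the small subunit of ribonucleotide reductase (25.1-fold). Next came CBLN2 (11.5-fold), CENPF (15.6-fold), ZWINT (12.7-fold) and the replicative helicase subunit MCM2 (11.0-fold).

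Grouped by list, 41 of 42 FOXM1 and G2/M genes fell in T47D-TR and 1 did not pass (41 fell adjusted over the list alone). Among them TPX2 fell from 4597 ± 100 to 595 ± 10.3, KIF11 from 3364 ± 105 to 379 ± 3.25 and CCNA2 from 1836 ± 27.3 to 142 ± 17.3. All 37 tested S-phase and E2F genes fell (37 adjusted over the list alone), among them RRM1 (8.95-fold). Camera gave adjusted p = 3.03e-18 and 4.06e-17 for these lists, and adjusted p = 0.114 for each with an estimated correlation. In comparisons with DMSO the latter form has 2 degrees of freedom or fewer. A call lost there shows neither correlation between the genes nor its absence. Of 36 genes of the ATF4 and unfolded protein response, 31 rose and 3 fell (31 and 3 adjusted over the list alone), with camera adjusted p = 1.09e-09 and adjusted p = 0.264 with an estimated correlation. PPP1R15A rose 16.5-fold and HERPUD1 8.05-fold. Of 28 p53 and growth arrest genes, 15 rose and 7 fell (16 and 7 adjusted over the list alone), with camera adjusted p = 0.0104 and adjusted p = 0.37 with an estimated correlation. Among them the cell cycle inhibitor CDKN1A rose from 1385 ± 65.8 to 11040 ± 299. Cholesterol biosynthesis genes fell in 20 of 26 cases and rose in 2 (20 and 3 adjusted over the list alone), with camera adjusted p = 4.98e-05 and adjusted p = 0.37 with an estimated correlation. Xenobiotic and NRF2 genes rose in 11 of 15 cases and fell in 2 (11 and 2 adjusted over the list alone), with camera adjusted p = 0.000976 and adjusted p = 0.264 with an estimated correlation. CYP1A1, a target of the aryl hydrocarbon receptor, rose 22.8-fold. Estrogen response genes fell in 15 of 22 cases and rose in 4 (15 and 5 adjusted over the list alone; camera adjusted p = 0.0404; adjusted p = 0.37 with an estimated correlation). STC2 fell 4.26-fold, and AREG, which is also on this list, rose 67.0-fold. Alongside these groups, all 8 tested replication-dependent histone transcripts, which mostly lack polyadenylation, rose (8 adjusted over the list alone; camera adjusted p = 0.000105; adjusted p = 0.264 with an estimated correlation). Of 13 mitochondrially encoded transcripts 3 fell (0 adjusted over the list alone), with no camera call (adjusted p = 0.33), and of 18 heat shock genes 4 rose and 6 fell (4 and 6 adjusted over the list alone), also without a call (adjusted p = 0.76).

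In all, MS177 changed 6516 of 10425 tested genes in T47D-TR (limma), 3245 higher and 3271 lower. The count moved by less than 1.5 times under every alternative run, and lay between 4779 and 5808 without any 1 of the 4 libraries.

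In BT-549, a triple-negative line, FOXM1 fell from 10050 ± 570 to 6306 ± 711, 1.59-fold, a log2 difference of -0.67 ± 0.13 (adjusted p = 0.0205, limma). MYC rose from 3784 ± 140 to 8841 ± 533, 2.34-fold (adjusted p = 0.00329, limma). EZH2 was 2975 ± 107 in DMSO and 3706 ± 131 with MS177, which missed the threshold (adjusted p = 0.087, limma). SUZ12 differed by -0.02 ± 0.13, EED by -0.38 ± 0.14 and EZH1 by 0.29 ± 0.15 (adjusted p = 0.929, 0.106 and 0.222, limma).

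GDF15 rose 246-fold in BT-549, from 130 ± 5.23 to 32060 ± 4278 (adjusted p = 0.000326, limma), and TRIB3, a target of ATF4, rose from 874 ± 59.3 to 22760 ± 1920. The other largest rises on the deposited scale, which compresses changes of low counts, were KLHDC7B (91.3-fold), the cytokine IL6 (30.7-fold), LAMP3 (132-fold) and NUPR1 (23.0-fold). The largest falls on that scale were ARPIN, an inhibitor of the Arp2/3 complex (1068 ± 77.9 to 60.8 ± 2.52), VASH1 (19.5-fold), VAV3 (10.8-fold), CCDC28B (18.2-fold), HAPLN3 (23.96-fold) and the proteoglycan CSPG4 (7.96-fold), with limma adjusted p between 0.000495 and 0.0017. ARPIN overlaps an annotated readthrough transcript, so its reads cannot all be assigned with certainty.

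Of 42 genes of the ATF4 and unfolded protein response in BT-549, 35 rose and 4 fell (35 and 5 adjusted over the list alone), with camera adjusted p = 1.29e-15 and adjusted p = 0.158 with an estimated correlation. ASNS, which makes asparagine, rose 13.0-fold and CHAC1 22.4-fold. FOXM1 and G2/M genes fell in 30 of 42 cases (36 adjusted over the list alone), with KIF20A down 2.63-fold (camera adjusted p = 4.79e-12; adjusted p = 0.158 with an estimated correlation). Of the S-phase and E2F genes 13 of 39 fell (16 adjusted over the list alone; camera adjusted p = 0.00133; adjusted p = 0.252 with an estimated correlation). Of 38 MYC and ribosome biogenesis genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with DDX21 up from 10020 ± 37.0 to 20020 ± 581 (camera adjusted p = 8.65e-07; adjusted p = 0.346 with an estimated correlation). HOX cluster genes fell in 14 of 21 cases and rose in 2 (14 and 2 adjusted over the list alone), with HOXC13 down 3.31-fold (camera adjusted p = 0.00011; adjusted p = 0.361 with an estimated correlation). Polycomb-marked developmental genes fell in 24 of 56 cases and rose in 5 (29 and 5 adjusted over the list alone), with camera adjusted p = 2.12e-06 and adjusted p = 0.196 with an estimated correlation. EN1 fell 3.80-fold and SOX8 11.4-fold. Mesenchymal and basal markers fell in 11 of 28 cases and rose in 2 (11 and 2 adjusted over the list alone), with camera adjusted p = 0.00198 and adjusted p = 0.361 with an estimated correlation. The collagen COL3A1 fell 2.77-fold and KRT5 7.10-fold. Interferon-stimulated genes fell in 14 of 30 cases and rose in 3 (15 and 3 adjusted over the list alone; camera adjusted p = 0.000713; adjusted p = 0.254 with an estimated correlation). MHC class I genes fell in 7 of 16 cases, among them the peptide transporter TAP1 (7 adjusted over the list alone; camera adjusted p = 0.000748; adjusted p = 0.361 with an estimated correlation). Cholesterol genes fell in 14 of 27 cases (14 adjusted over the list alone; camera adjusted p = 1.98e-05; adjusted p = 0.196 with an estimated correlation). Lysosome genes rose in 11 of 31 cases and fell in 2 (14 and 2 adjusted over the list alone), with MAP1LC3B up 3.19-fold (camera adjusted p = 0.000718; adjusted p = 0.361 with an estimated correlation). Beside these groups, 7 of 13 mitochondrially encoded transcripts fell (11 adjusted over the list alone; camera adjusted p = 7.11e-05; adjusted p = 0.361 with an estimated correlation). Of 10 histone transcripts 4 rose (4 adjusted over the list alone), H2AC6 by a log2 difference of 1.01 (camera adjusted p = 0.0371; adjusted p = 0.413 with an estimated correlation).

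MS177 changed 3953 of 14474 tested genes in BT-549 (limma), 1874 higher and 2079 lower. Without DMSO replicate 1 the count was 2527, and without DMSO replicate 2 it was 2445.

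In T47D, FOXM1 stood at 7708 ± 176 in DMSO and 2210 ± 309 with MS177, a 3.49-fold lower mean and a log2 difference of -1.80 ± 0.28, which missed the threshold (adjusted p = 0.131, limma). EZH2 stood at 1452 ± 28.5 and 1719 ± 192, EED at 1681 ± 122 and 910 ± 129, and MYC at 2058 ± 75.5 and 3213 ± 1340 (adjusted p = 0.651, 0.227 and 0.474, limma). All 42 FOXM1 and G2/M genes were lower with MS177 and 0 passed over all genes (limma). Adjusted over the list alone, 38 were lower (median log2 difference -1.92; camera adjusted p = 2.23e-25; adjusted p = 0.141 with an estimated correlation). Likewise 39 of 39 S-phase and E2F genes were lower, 0 past the threshold over all genes and 39 adjusted over the list alone (median -2.22; camera adjusted p = 7.29e-30; adjusted p = 0.122 with an estimated correlation). Of 42 genes of the ATF4 and unfolded protein response, 36 were higher, 20 of them past the threshold adjusted over the list alone (median 1.33; camera adjusted p = 7.82e-13; adjusted p = 0.157 with an estimated correlation). Of 31 p53 and growth arrest genes 25 were higher, 13 adjusted over the list alone (median 1.09; camera adjusted p = 3.34e-06; adjusted p = 0.201 with an estimated correlation). Cholesterol genes were lower in 22 of 26 cases, 5 adjusted over the list alone (median -0.96; camera adjusted p = 1.19e-06; adjusted p = 0.163 with an estimated correlation). The MS177 libraries of T47D stood apart from each other, with a correlation across genes of 0.863 against 0.990 for the DMSO pair (genes are not independent replicates).

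Over all genes, MS177 against DMSO in T47D gave 0 of 18146 genes by limma, 0 by limma without the mean trend and 0 by limma voom, with 3247 genes at an unadjusted p under 0.05. In a fit of all T47D libraries 3150 genes passed. The count was 12368 without MS177 replicate 2, 8784 without MS177 replicate 1, 70 without DMSO replicate 2 and 48 without DMSO replicate 1. A fit with 1 MS177 library takes its spread from the DMSO pair, which lay closer together, so the 2 larger counts may come from that small spread.

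**Figure D2:**
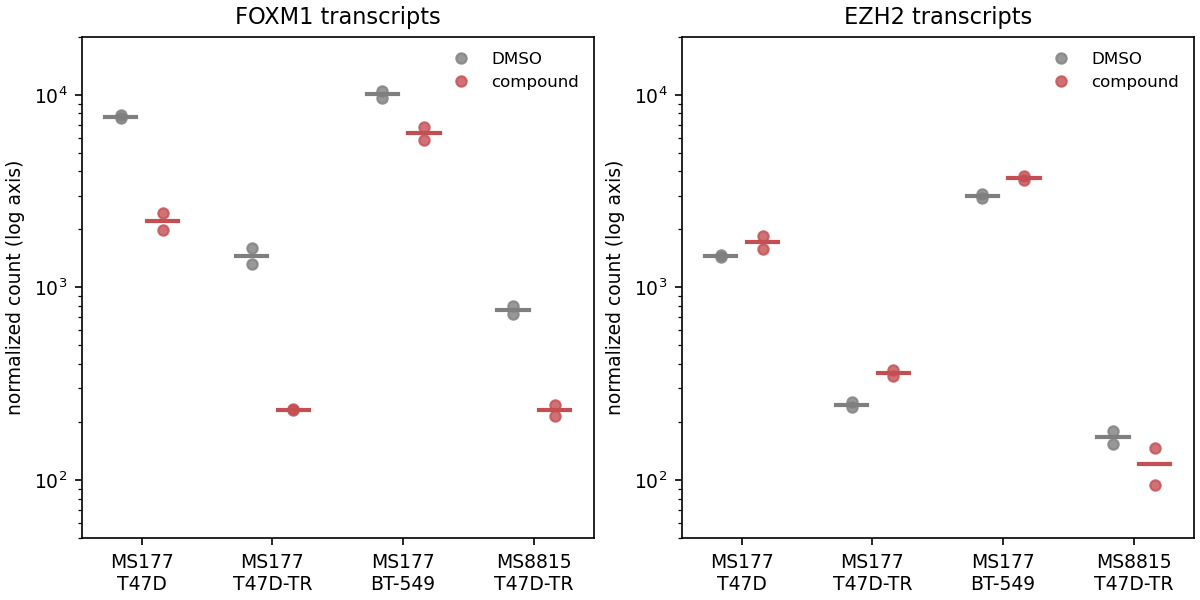
Normalized counts (log axis) of FOXM1 and EZH2 with MS177 or MS8815 and in the DMSO libraries of the same table; points are libraries and lines are means. FOXM1 means were 7708 and 2210 in T47D, 1459 and 233 in T47D-TR, 10050 and 6306 in BT-549, and 763 and 230 with MS8815, and EZH2 means with compound lay above DMSO for MS177 and below it for MS8815.

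Direct comparisons of MS177 with its negative controls and with C24, at 2.5 uM and 48 h each, asked whether these responses belong to the degrader. FOXM1 was lower with MS177 than with MS177-N1, MS177-N2 and C24 in every line. In T47D the log2 differences were -1.81, -1.79 and -1.71 (adjusted p = 0.00783, 0.00248 and 0.00266, limma; SE 0.155 to 0.189), with 1 library of MS177-N1. In fits of the compared libraries alone they did not pass (adjusted p = 1, 0.154 and 0.13, limma). The second was also lost without either MS177-N2 replicate (smallest adjusted p = 0.0525, limma) and the third without either C24 replicate (smallest adjusted p = 0.0518, limma). They were -2.40, -2.65 and -2.41 in T47D-TR (adjusted p = 4.8e-06, 3.37e-06 and 5.04e-06, limma; SE 0.154), and -0.83, -0.87 and -0.82 in BT-549 (adjusted p = 0.00152, 0.00111 and 0.00142, limma; SE 0.131). EZH2 transcripts were higher with MS177 than with MS177-N2 and C24 in T47D-TR (log2 differences 0.61 and 0.52, adjusted p = 0.00636 and 0.014, limma) and in BT-549 (0.36 and 0.34, adjusted p = 0.0202 and 0.0262, limma). Against MS177-N1 the EZH2 difference was 0.28 in T47D-TR (95% interval -0.03 to 0.60) and 0.25 in BT-549 (0.03 to 0.48), which missed the threshold after adjustment (adjusted p = 0.122 and 0.0787, limma). In T47D it was 0.10 to 0.23 against the 3 compounds, the widest interval running from -0.33 to 0.53. EED was lower with MS177 than with MS177-N1, MS177-N2 and C24 in T47D-TR (-1.58, -0.98 and -1.37; adjusted p = 0.00418, 0.0408 and 0.00915, limma) and in T47D (-0.92, -0.80 and -0.84; adjusted p = 0.0417, 0.023 and 0.0182, limma). The T47D calls were lost in fits of the compared libraries alone (adjusted p = 1, 0.252 and 0.22, limma). In T47D-TR the call against MS177-N2 was lost with quantile scaling, and those against MS177-N2 and C24 were lost without MS177 replicate 1 (largest adjusted p = 0.195, limma). In BT-549 it differed by -0.13, 0.06 and -0.01 (adjusted p = 0.521, 0.794 and 0.977, limma), the intervals running from -0.47 to 0.39.

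The lipocalin LCN2 was 6.35 to 6.98 log2 units higher with MS177 than with each control in T47D and 6.56 to 8.16 in T47D-TR. INHBE was 6.41 to 6.81 units higher in T47D-TR and 5.18 to 6.65 in BT-549, where GDF15 was 6.68 to 7.79 units higher. The gap junction protein GJA1 and the dNTP hydrolase SAMHD1 were both listed at 0 with MS177 in T47D-TR. The other 3 compounds left 188 to 328 normalized counts of GJA1, and MS177-N2 and C24 left 144 and 111 of SAMHD1. SAMHD1 was not among the named falls against MS177-N1. ARPIN differed between MS177 and MS177-N1 by -4.62 ± 0.62 log2 units in T47D and -5.81 ± 0.18 in T47D-TR (adjusted p = 0.013 and 2.96e-07, limma). Between the same compounds the kinase IKBKE differed by -4.66 ± 0.21 in BT-549 (adjusted p = 1.58e-06, limma).

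**Figure D3:**
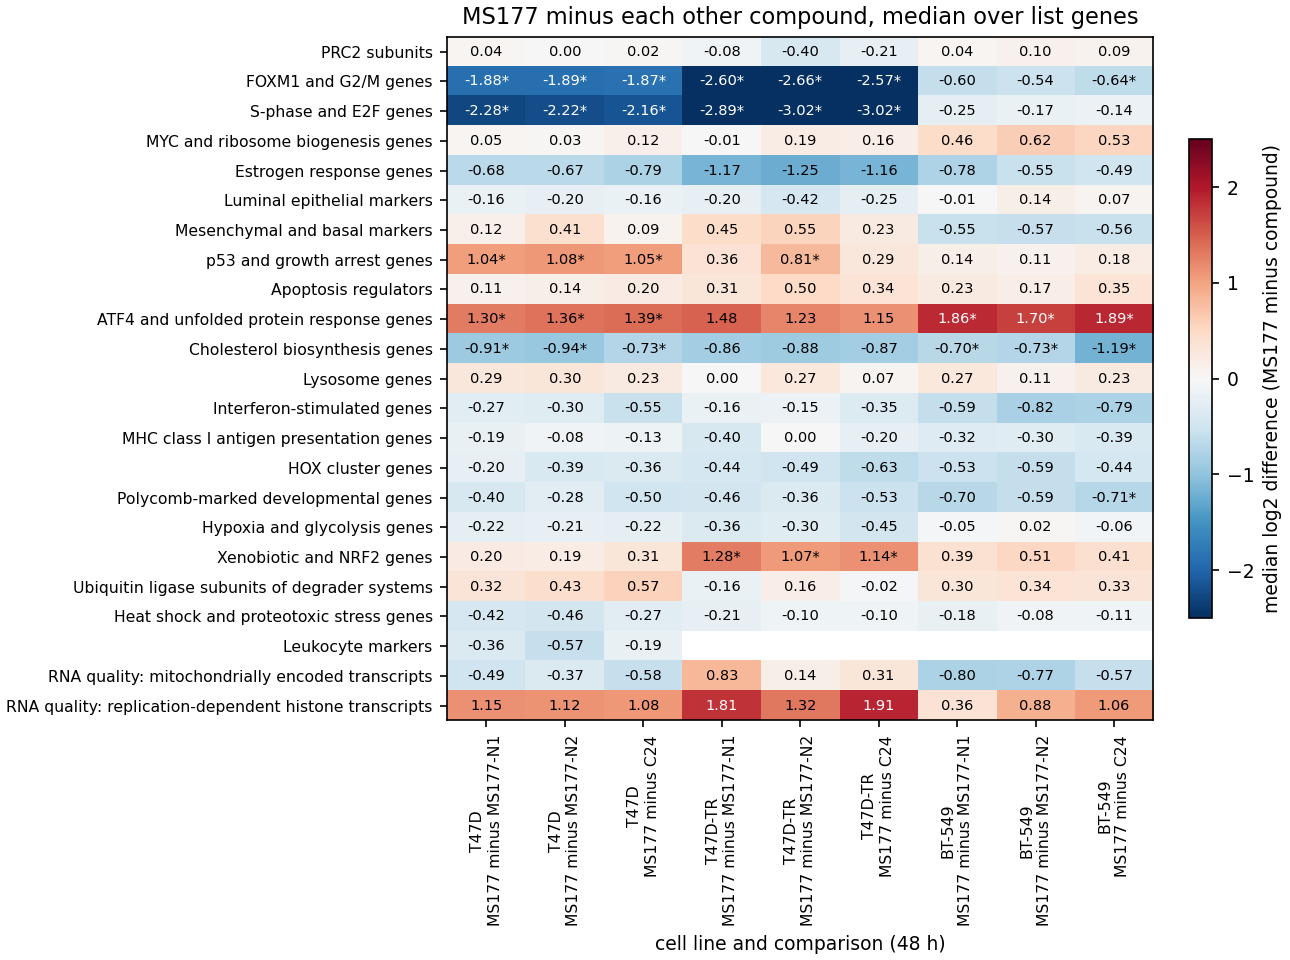
Median log2 difference over the genes of each list, MS177 minus the compound named below each column, by cell line at 48 h. Red is higher with MS177, blue lower, and a star marks lists with an adjusted p under 0.05 by camera with an estimated correlation. The FOXM1 and G2/M medians run from -2.66 to -2.57 in T47D-TR, from -1.89 to -1.87 in T47D and from -0.64 to -0.54 in BT-549.

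By list, the FOXM1 and G2/M genes had medians of -1.87 to -1.89 against the 3 other compounds in T47D and -2.57 to -2.66 in T47D-TR, and the S-phase and E2F genes -2.16 to -2.28 and -2.89 to -3.02. These calls held with an estimated correlation (largest adjusted p = 0.0107). All T47D list calls here rest on the fit of all T47D libraries. Gene calls of that fit, FOXM1 among them, were lost in fits of the compared libraries alone. Such fits were not run for lists, so the T47D list calls are less certain than those of the other lines. In BT-549 the FOXM1 and G2/M medians were -0.60, -0.54 and -0.64 against MS177-N1, MS177-N2 and C24. With an estimated correlation the last call held (adjusted p = 0.0452) while the first and second did not (adjusted p = 0.054 and 0.0821). The S-phase and E2F medians there were -0.25, -0.17 and -0.14, calls that did not hold (smallest adjusted p = 0.138). Genes of the ATF4 and unfolded protein response were higher with MS177 by medians of 1.70 to 1.89 in BT-549 and 1.30 to 1.39 in T47D, calls that held with an estimated correlation (largest adjusted p = 0.0101). In T47D-TR the medians were 1.15 to 1.48, and the calls did not hold (adjusted p = 0.0711 to 0.0867). Cholesterol genes were lower by 0.70 to 1.19 in BT-549 (medians -0.70, -0.73 and -1.19) and by medians of -0.73 to -0.94 in T47D, with adjusted p of at most 0.0374 with an estimated correlation. In T47D-TR the medians were -0.86, -0.88 and -0.87, and the calls did not hold (adjusted p = 0.107, 0.0874 and 0.0864 with an estimated correlation). NRF2 and xenobiotic genes were higher in T47D-TR (medians 1.28, 1.07 and 1.14; adjusted p = 0.0437, 0.0495 and 0.0474 with an estimated correlation), while in BT-549 their calls did not hold (medians 0.39, 0.51 and 0.41; smallest adjusted p = 0.0743) and in T47D they were not called. The p53 and growth arrest genes were higher in T47D (medians 1.04, 1.08 and 1.05; adjusted p = 0.0286, 0.0366 and 0.0374 with an estimated correlation). In T47D-TR their medians were 0.36, 0.81 and 0.29, and the second call alone held (adjusted p = 0.0867, 0.0495 and 0.0769 with an estimated correlation). In BT-549 they were not called (camera adjusted p = 0.0995, 0.144 and 0.077). Polycomb-marked genes were lower with MS177 than with C24 in BT-549 in 51 of 61 cases, with 39 lower and 5 higher past the threshold, 40 and 6 adjusted over the list alone (median -0.71; camera adjusted p = 1.07e-08; adjusted p = 0.0452 with an estimated correlation). The same list was lower than with MS177-N1 in 49 of 61 cases, with 36 lower and 3 higher past the threshold, 38 and 4 adjusted over the list alone (median -0.70; camera adjusted p = 1.05e-07). It was lower than with MS177-N2 in 48, with 33 lower and 5 higher past the threshold, 36 and 5 adjusted over the list alone (median -0.59; camera adjusted p = 1.53e-06). Neither call held (adjusted p = 0.056 and 0.0821 with an estimated correlation). Camera calls for the other lists of biological processes did not hold either (smallest adjusted p = 0.0874 with an estimated correlation, estrogen response genes in T47D-TR).

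Lists chosen to follow RNA quality also differed between MS177 and the other compounds, and none of these calls held with an estimated correlation. Whether they followed RNA quality or a response of the cells was not tested. Histone transcripts were higher than with MS177-N1, MS177-N2 and C24 by medians of 1.15, 1.12 and 1.08 in T47D, with 5, 7 and 7 of 13 higher past the threshold and 7, 8 and 7 adjusted over the list alone (camera adjusted p = 0.000939, 0.00091 and 0.00131; adjusted p = 0.0683, 0.0678 and 0.0739 with an estimated correlation). In T47D-TR the medians were 1.81, 1.32 and 1.91, with 9, 8 and 9 of 13 higher and 3, 2 and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.0107, 0.0132 and 0.00547; adjusted p = 0.145, 0.147 and 0.111 with an estimated correlation). In BT-549 they were 0.36, 0.88 and 1.06, with 5, 5 and 7 higher and 5, 5 and 8 adjusted over the list alone (camera adjusted p = 0.011, 0.00859 and 0.000145; adjusted p = 0.293, 0.304 and 0.192 with an estimated correlation). Mitochondrially encoded transcripts were lower in BT-549 by medians of -0.80, -0.77 and -0.57, with 10, 12 and 7 of 13 lower and 11, 12 and 7 adjusted over the list alone (camera adjusted p = 0.000175, 0.000232 and 0.00586; adjusted p = 0.293, 0.304 and 0.409 with an estimated correlation).

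MS177 differed from MS177-N1, MS177-N2 and C24 at 7626, 6965 and 7227 of 15027 genes in T47D-TR, at 5414, 6086 and 5832 of 16345 in BT-549, and at 1485, 2894 and 3349 of 17341 in T47D (limma). The T47D-TR counts moved by less than 1.5 times under every alternative run. In BT-549 they fell to 3252, 3732 and 3816 without MS177 replicate 2, to 3465 without MS177-N1 replicate 2, to 3830 without MS177-N2 replicate 1 and to 3351 without C24 replicate 1. The MS177-N1 comparison there gave 3179 in a fit of its 4 libraries. In T47D a fit of the libraries of both compounds gave 44, 0 and 0 genes (2951 and 3218 at an unadjusted p under 0.05 for the last pair). Leaving out MS177 replicate 2 gave 12022, 12871 and 12998, and MS177 replicate 1 gave 9315, 9643 and 9917, while leaving out either MS177-N2 replicate gave 80, and leaving out C24 replicate 1 or 2 gave 104 or 145.

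The responses to MS177 were then compared between lines, with a test of the difference itself on log2 normalized counts. In the T47D-TR tables alone the counts were not whole reads, and fewer symbols matched the annotation. Cell line and processing of the tables therefore differ together in comparisons with T47D-TR and cannot be told apart. FOXM1 fell further in T47D-TR than in BT-549, by a difference of -1.96 ± 0.18 (adjusted p = 0.000276, limma), while the rise of MYC was smaller there (-0.84 ± 0.15; adjusted p = 0.00444, limma). The response differed at 3885 of 11945 genes between T47D-TR and BT-549 (2522 without BT-549 DMSO replicate 1), at 254 of 14739 between T47D and BT-549 and at 4 of 12755 between T47D and T47D-TR. The counts of 254 and 4 were 0 without any 1 DMSO library, and without any 1 MS177 library of the line set against T47D, with at least 1318 and 814 genes at an unadjusted p under 0.05. They rose to 7103 and 5507 without T47D MS177 replicate 2 and to 2189 and 1761 without T47D MS177 replicate 1. Of the genes tested in both tables, 913 rose with MS177 in T47D-TR and in BT-549 against 392 by independence, 830 fell in both against 373, and 198 moved in opposite directions, out of 9424.

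C24 and the negative controls were compared with DMSO to ask which transcripts these compounds change. FOXM1 and EZH2 passed the threshold with none of these compounds in any line. With C24 in BT-549, the desaturase SCD rose from 16270 ± 742 to 51660 ± 10300 (adjusted p = 0.00997, limma), and HMGCS1, an enzyme of sterol synthesis, from 1898 ± 32.2 to 5445 ± 448 (adjusted p = 0.00352, limma). Of 27 cholesterol biosynthesis genes 8 rose with C24 in BT-549 and 23 did so adjusted over the list alone (median 0.68; camera adjusted p = 3.42e-28; adjusted p = 0.351 with an estimated correlation). In T47D, C24 raised PIP, a secreted protein of luminal cells, from 5598 ± 139 to 10130 ± 623 (adjusted p = 1.29e-05, limma), SHISA2 2.02-fold and CLIC6 2.01-fold. It lowered HR 1.35-fold, IER3 1.32-fold and DDX46 1.25-fold. Of 28 polycomb-marked genes tested there, 24 were higher and 0 passed over all genes, with 1 adjusted over the list alone (median 0.07; camera adjusted p = 0.00264; adjusted p = 0.495 with an estimated correlation). The 1 gene past the threshold with C24 in T47D-TR, LMBRD1, named after its values were seen, was listed at 0 with C24 and at 192 in DMSO (adjusted p = 0.0364, limma).

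C24 changed 100 of 11803 genes in T47D (95 higher), 18 of 13394 in BT-549 (16 higher) and 1 of 11748 in T47D-TR (limma). In T47D the count was 0 in the fit of all libraries (211 at an unadjusted p under 0.05), 45 by limma voom and 45 by limma without the mean trend. It was 2390 and 367 without DMSO replicate 1 or 2, and 52 and 46 without C24 replicate 1 or 2. In BT-549 it was 36 and 245 without C24 replicate 1 or 2, and 55 and 778 without DMSO replicate 1 or 2. In T47D-TR it was 118 and 4 without C24 replicate 1 or 2, and 2 and 5 without DMSO replicate 1 or 2.

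MS177-N2 in BT-549 raised APOE, a lipid carrier, from 172 ± 63.7 to 809 ± 85.2, the adhesion molecule L1CAM from 739 ± 99.0 to 2806 ± 113, and FLNC 2.73-fold (limma adjusted p of at most 3.06e-05). It lowered ARPIN 12.9-fold, TK2, a mitochondrial thymidine kinase, from 971 ± 3.32 to 163 ± 35.4, and CCDC28B 5.11-fold (limma adjusted p of at most 8.68e-07). Its 491 changed genes of 14356 (295 higher) held COL1A1, up 2.06-fold, FN1, up 1.78-fold, and NUPR1, up 2.13-fold. In T47D-TR, MS177-N2 changed 19 of 10852 genes, with CLN3, a lysosomal membrane protein, up from 1382 ± 73.2 to 3179 ± 39.7 and ARPIN (13.6-fold), FXYD3 (4.43-fold) and the vault protein MVP (5.09-fold) down (limma adjusted p of at most 0.0199). In T47D it changed 0 of 10432 genes by limma, by limma without the mean trend and by limma voom, with 522 at an unadjusted p under 0.05. The BT-549 count was 99 in the fit of all libraries, 172 and 1383 without DMSO replicate 1 or 2 and 121 without MS177-N2 replicate 1. In T47D-TR it was 11 without either DMSO replicate and 43 without MS177-N2 replicate 2. In T47D it was 952 and 304 without DMSO replicate 1 or 2, and 18 and 15 without MS177-N2 replicate 1 or 2.

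The related compounds were compared by a contrast with no DMSO library in it, although the DMSO libraries set the common scale and entered the spread. This contrast, added after the values were seen, set MS177-N2 against the mean of MS177-N1 and C24. It gave 58 genes in T47D-TR (44 lower), 140 in BT-549 (84 lower) and 0 in T47D (284 at an unadjusted p under 0.05; limma). Of 12001 genes tested in the 3 lines, 20 were lower in both T47D-TR and BT-549 against 0.21 by independence, and CLN3 and USP36 were higher in both. IKBKE, a kinase of innate immune signalling, differed by -4.21 ± 0.56 log2 units in T47D-TR and -2.61 ± 0.18 in BT-549 (adjusted p = 0.0204 and 0.000191, limma), and the lipase ABHD6 by -3.10 ± 0.27 and -2.99 ± 0.19 (adjusted p = 0.00169 and 0.000126, limma). In T47D the same differences were -2.43 ± 0.42 and -2.59 ± 0.41. With MS177, 18 of the 20 lay below DMSO in all 3 lines, the exceptions being SDSL and SYT12.

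**Figure D4:**
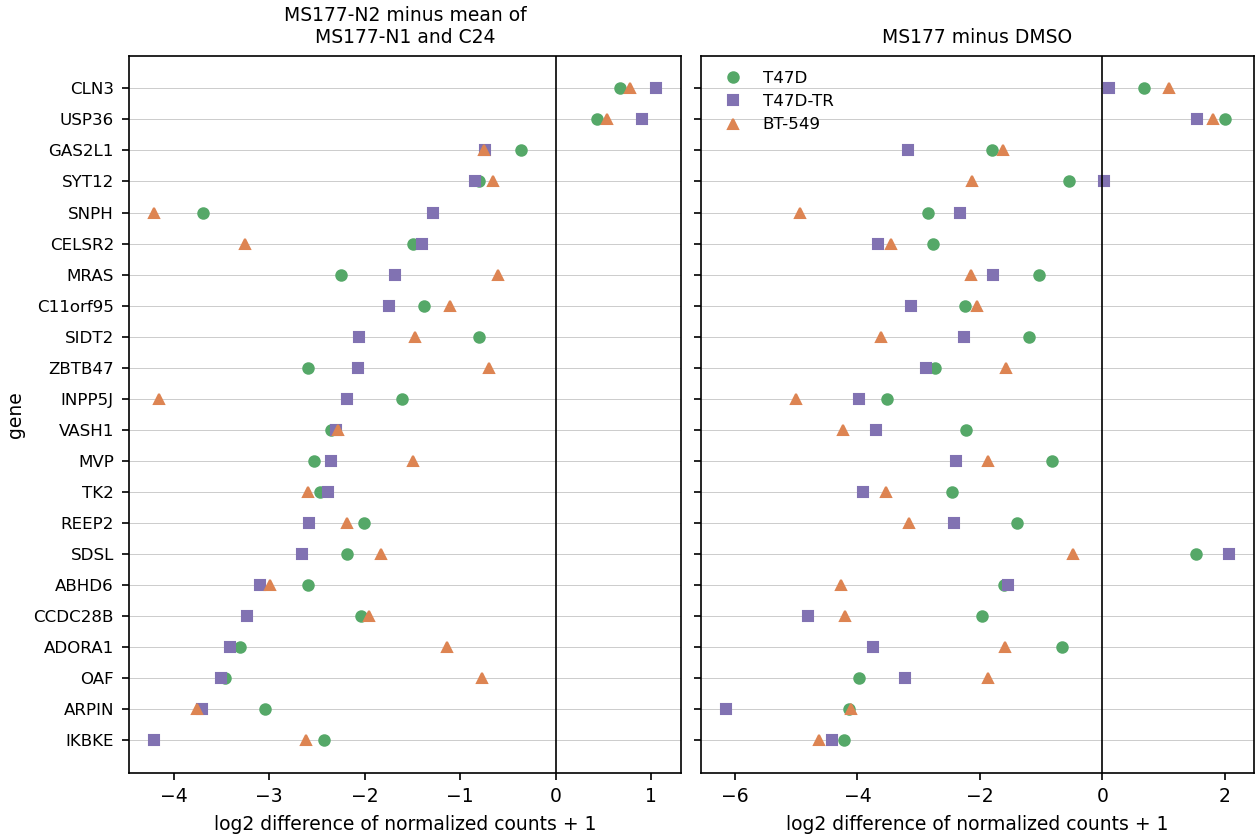
Log2 differences of normalized counts + 1 for the 22 genes past the threshold in the same direction in T47D-TR and BT-549 when MS177-N2 was compared with the mean of MS177-N1 and C24 (left), and the differences of MS177 from DMSO for the same genes (right); colours and shapes mark the cell lines. On the left, 20 genes lie below 0 and 2 above it in all lines, and on the right SDSL lies at 1.53 in T47D and 2.06 in T47D-TR.

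MS177-N1 changed 2906 of 10578 genes in T47D-TR (limma, 1573 higher), with NUCKS1, a chromatin protein, up from 6753 ± 56.0 to 24740 ± 3299 (adjusted p = 0.000165, limma), RPS27A 3.66-fold and the noncoding BCYRN1 4.38-fold. HIST2H2AA3 was listed at 0 with MS177-N1 and at 262 ± 174 in DMSO. Of 13 mitochondrially encoded transcripts tested, 10 fell and 3 did not pass (12 fell adjusted over the list alone), with MT-CYB down 2.996-fold and MT-ATP6 down 2.96-fold (camera adjusted p = 8.31e-07; adjusted p = 0.883 with an estimated correlation). Of 42 FOXM1 and G2/M genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), and of 39 S-phase genes 6 rose and 2 fell (5 and 2 adjusted over the list alone). The count was 5 in the fit of all T47D-TR libraries, 215 without DMSO replicate 2 and 878 without MS177-N1 replicate 2. MS177-N1 changed 0 of 13934 genes in BT-549 by limma, by limma without the mean trend and by limma voom (309 at an unadjusted p under 0.05). The count there was 6 and 20 without DMSO replicate 1 or 2 and 22 and 9 without MS177-N1 replicate 1 or 2. In T47D its 1 library gave 21 of 11716 genes, 9 higher and 12 lower (3 and 2 with quantile scaling), and 0 genes in the fit of all T47D libraries (71 at an unadjusted p under 0.05). The largest rise was SMIM11A, at 703 in that library and at 435 and 262 in the DMSO libraries, and 1 library cannot show an effect of the compound on it.

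With MS8815, given to T47D-TR cells for 30 h, FOXM1 fell from 763 ± 53.1 to 230 ± 21.2, 3.31-fold (adjusted p = 0.0338, limma), and EZH2 was 167 ± 18.1 in DMSO and 121 ± 36.9 with MS8815 (adjusted p = 0.354, limma). HMOX1, which degrades heme, rose 52.1-fold (93.9 ± 10.2 to 4895 ± 2269), and GDF15 44.9-fold (82.1 ± 5.97 to 3683 ± 7.48). The chaperone HSPA6 rose from 9.25 ± 0.07 to 1512 ± 140, EPGN from 2.13 ± 2.27 to 1355 ± 187, MAP1B from 7.49 ± 3.67 to 1179 ± 618 and the cystine transporter SLC7A11 22.2-fold (limma adjusted p of at most 0.0307). Among the largest falls on the deposited scale were LRRC15 (11.5-fold), GJA1 (9.645-fold), PDZK1 (10.9-fold), SERPINA6 (8.05-fold) and PGLYRP2 (7.70-fold), with limma adjusted p of at most 0.0338.

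Of 18 heat shock genes 8 rose with MS8815 (13 adjusted over the list alone), with camera adjusted p = 5.76e-09 and adjusted p = 0.237 with an estimated correlation. HSPA1A rose from 2755 ± 202 to 39920 ± 7997. In MS8815 replicate 1 the heat shock gene HSP90AA1 alone took 12.4% of all normalized counts. NRF2 and xenobiotic genes rose in 10 of 18 cases (10 adjusted over the list alone), with AKR1C1 up from 3.09 ± 1.90 to 238 ± 26.0 (camera adjusted p = 3.5e-08; adjusted p = 0.353 with an estimated correlation). Genes of the ATF4 and unfolded protein response rose in 14 of 38 cases (23 rose and 2 fell adjusted over the list alone), with HSPA5 up 13.9-fold (camera adjusted p = 9.28e-08; adjusted p = 0.353 with an estimated correlation). FOXM1 and G2/M genes fell in 18 of 42 cases (36 adjusted over the list alone), with PLK1 down 3.53-fold (camera adjusted p = 8.83e-16; adjusted p = 0.353 with an estimated correlation). S-phase genes fell in 10 of 39 cases (22 adjusted over the list alone; camera adjusted p = 8.38e-10; adjusted p = 0.237 with an estimated correlation). Estrogen response genes fell in 7 of 26 cases and rose in 1 (14 and 1 adjusted over the list alone), with PDZK1 among them (camera adjusted p = 4.37e-06; adjusted p = 0.237 with an estimated correlation). Interferon-stimulated genes rose in 8 of 28 cases (11 rose and 2 fell adjusted over the list alone), with RSAD2 up from 6.48 ± 0.73 to 275 ± 23.5 (camera adjusted p = 0.00817; adjusted p = 0.529 with an estimated correlation). Mitochondrially encoded transcripts were higher with MS8815 than with DMSO in 12 of 13 cases, 0 past the threshold and 0 adjusted over the list alone (median 0.69; camera adjusted p = 0.00817; adjusted p = 0.651 with an estimated correlation).

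MS8815 changed 754 of 12067 genes (limma, 394 higher), while MS8815-N and EPZ-6438 changed 0 of 10169 and 0 of 12673 by limma with or without the mean trend, with 289 and 157 at an unadjusted p under 0.05. In MS8815-N replicate 2, 44.3% of genes lay at the lowest value, against 1.02% in replicate 1. The MS8815 count was 11 in the fit of all libraries and 434 without a filter. It was 5721 and 6988 without MS8815 replicate 1 or 2, and 142 and 138 without DMSO replicate 3 or 4. Without MS8815-N replicate 1 or 2, MS8815-N gave 7523 or 4321 genes, and EPZ-6438 gave 5050 or 17 without its replicate 1 or 2, and 14 or 17 without DMSO replicate 3 or 4.

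Set against its own controls, MS8815 was higher than MS8815-N at 8 of 13934 genes and than EPZ-6438 at 15, with no gene lower (limma). With quantile scaling 50 genes were higher and 16 lower than with MS8815-N, and 37 and 7 than with EPZ-6438. GDF15 was higher by 4.34 ± 0.40 and 4.68 ± 0.40 log2 units (adjusted p = 0.023 and 0.0213, limma), SLC7A11 by 4.23 ± 0.38 and 4.41 ± 0.38 (the same adjusted p, limma), and HSPA1A was 3.84 ± 0.30 above MS8815-N (adjusted p = 0.023, limma). FOXM1 differed by -0.14 from MS8815-N (95% interval -1.83 to 1.55) and by -1.36 from EPZ-6438 (-3.06 to 0.33), so that neither a fall nor its absence was shown. FOXM1 and G2/M genes were lower than with MS8815-N in 38 of 42 cases, 0 of them past the threshold over all genes and 24 adjusted over the list alone (median -1.13; camera adjusted p = 5.03e-22), a call that did not hold (adjusted p = 0.0758 with an estimated correlation). FOXM1 and G2/M genes were lower than with EPZ-6438 in 40 of 42 cases, 0 of them past the threshold over all genes and 26 adjusted over the list alone (median -1.35; camera adjusted p = 2.11e-29; adjusted p = 0.0393 with an estimated correlation). The S-phase and E2F list was lower than with MS8815-N in 31 of 39 cases and than with EPZ-6438 in 38, with 0 past the threshold over all genes and 9 and 8 adjusted over the list alone (medians -0.93 and -1.0; camera adjusted p = 5.9e-12 and 2.52e-15), and both calls held (adjusted p = 0.0233 and 0.0145 with an estimated correlation). Heat shock genes had medians of 2.21 and 2.05, with 2 and 3 of 18 higher past the threshold and 14 and 12 adjusted over the list alone. Genes of the ATF4 and unfolded protein response had medians of 1.33 and 1.21, with 2 and 4 of 38 higher and 15 and 10 adjusted over the list alone. Estrogen response genes had medians of -0.77 and -1.10, with 0 of 28 passing and 5 lower and 1 higher, and 4 and 1, adjusted over the list alone. These 3 calls held against EPZ-6438 (adjusted p = 0.0393 for each with an estimated correlation) and not against MS8815-N (adjusted p = 0.153, 0.196 and 0.0673 with an estimated correlation). NRF2 and xenobiotic genes had medians of 3.01 and 1.28. Of 20, 2 and 4 were higher, with 12 and 5 adjusted over the list alone. Neither call held (adjusted p = 0.214 and 0.14 with an estimated correlation). All sizes against MS8815-N rest in part on its replicate 2, where 44.3% of genes lay at the lowest value. EZH2, for instance, differed by 3.25 log2 units between MS8815 and MS8815-N, at means of 121 and 77.9 normalized counts. All 13 mitochondrially encoded transcripts, a list chosen to follow RNA quality, were higher than with MS8815-N and with EPZ-6438, 0 past the threshold and 0 adjusted over the list alone. Their medians were 0.71 and 0.95 (camera adjusted p = 0.0529 and 7.9e-07), and the second call did not hold (adjusted p = 0.323 with an estimated correlation).

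Leaving out the 3 libraries that stood apart (MS8815 replicate 1, MS8815-N replicate 2 and EPZ-6438 replicate 2) gave 6583 and 5122 genes. Leaving out MS8815 replicate 1 or 2 gave 0 in both comparisons (1154 and 979, and 816 and 815, at an unadjusted p under 0.05). Leaving out MS8815-N replicate 1 or 2 gave 7722 or 74, and leaving out EPZ-6438 replicate 1 or 2 gave 0 (706 or 704 at an unadjusted p under 0.05). A fit of the 4 libraries of both compounds gave 28 and 99 genes, and the deposited log2 values gave 0 and 0 (2613 and 1628 at an unadjusted p under 0.05).

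MS177 and MS8815 were given to T47D-TR for different times and with different DMSO shares, so their values are set side by side. Of 10345 genes tested in both tables, 223 rose with both compounds against 96.7 by independence, 302 fell with both against 107, and 41 moved in opposite directions. The correlation of log2 differences across genes was 0.595 (Pearson; genes are not independent replicates). Without a filter, 328 genes in place of 525 passed in the same direction with both. CDKN1A rose 7.97-fold with MS177 and 2.79-fold with MS8815. HSPA1A fell 1.67-fold with MS177 (adjusted p = 0.00125, limma) and rose 14.5-fold with MS8815 (adjusted p = 0.0203, limma).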

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

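The comparisons of the MS177 response between lines were planned before the data were examined. The comparison of the MS177-N1 response was chosen after its result was seen, as were all tests below except those that removed a trend with gene length and GC content. Values are differences of log2 changes against DMSO, and the pattern noted in each case is a difference between cell lines. With T47D-TR, the processing of the tables differs along with the line.

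Between T47D and T47D-TR the response differed at 4 genes (limma). SAMHD1 differed by 6.217 ± 0.367 and GJA1 by 6.139 ± 0.428 (adjusted p = 0.00858 and 0.0107), both listed at 0 with MS177 in T47D-TR, so these sizes rest on the 1 added to each count. With the deposited log2 values GJA1 differed by -0.443 (adjusted p = 0.721) and 0 genes passed (1533 at an unadjusted p under 0.05). B3GNT3 and IL6R responded more positively in T47D-TR, with differences of -4.227 ± 0.372 and -4.177 ± 0.292 (adjusted p = 0.0315 and 0.0107). By list, medians were 0.88 for FOXM1 and G2/M genes, 0.63 for S-phase and E2F genes, -1.03 for mesenchymal markers and -0.79 for NRF2 genes. With an estimated correlation none of these list calls held (smallest adjusted p = 0.0602).

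Between T47D and BT-549 it differed at 254 genes (limma). More positive in T47D were RBMS3 (6.069), LCN2 (5.284), CCDC184 (5.131) and PRR16 (4.613), and more negative were PDGFB (-5.12), STC2 (-3.94), ITPKA (-3.91) and ESRP1 (-3.814), with limma adjusted p between 0.0165 and 0.0323. STC2, a stress-induced glycoprotein, changed by -1.34 in T47D and 2.60 in BT-549. Medians were -1.25 for FOXM1 and G2/M genes and -2.05 for S-phase and E2F genes, calls that held with an estimated correlation (adjusted p = 0.0142 and 0.0027). Medians that did not hold were -0.33 for MYC, -0.34 for ATF4 and -0.40 for cholesterol genes, 0.80 for mesenchymal, 0.54 for p53, 0.74 for interferon, 0.52 for MHC class I, 0.61 for HOX and 0.53 for polycomb-marked genes, and 0.74 for histone transcripts (smallest adjusted p = 0.117).

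Between T47D-TR and BT-549 it differed at 3885 genes (limma). FOXM1 differed by -1.962 ± 0.182, MYC by -0.842 ± 0.148 and SUZ12 by -0.555 ± 0.154 (adjusted p = 0.000276, 0.00444 and 0.0281). More positive in T47D-TR were LCN2 (6.928), MCAM (6.778), SULF2 (6.624) and the transcription factor SNAI2 (6.498). More negative were GJA1 (-7.262), SAMHD1 (-6.789), PRSS53 (-4.793) and UBE2T, a ubiquitin-conjugating enzyme of DNA repair (-4.726). Medians were -2.01 for FOXM1 and G2/M genes and -2.76 for S-phase and E2F genes, which held with an estimated correlation (adjusted p = 0.00453 for each). Medians that did not hold were -0.27 for MYC and -0.38 for cholesterol genes, 1.15 for mesenchymal, 0.59 for p53, 0.56 for interferon, 0.39 for MHC class I and 0.68 for polycomb-marked genes, and 0.51 for mitochondrially encoded transcripts (smallest adjusted p = 0.231). The response to MS177-N1 differed between T47D-TR and BT-549 at 12 of 11697 genes, with 3996 at an unadjusted p under 0.05.

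In T47D the pair of MS177 libraries differed from each other more than the DMSO pair did, with an SD over genes of 0.99 and a ratio to the DMSO pair of 3.75. Taking a trend with gene length and GC content out of each library left a ratio of 3.59, and the 10 most abundant genes took no larger share with MS177 (ratio of the highest shares 0.96), so neither accounts for the spread. A library left untreated by mistake would lack the cell cycle response, yet the S-phase and E2F median was -2.22 in the library nearer to DMSO and -2.24 in the other, with 39 of 39 genes lower in both. A culture further along in the response, a difference in handling and an unnamed batch all stay open. No biological explanation was tested.

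In T47D-TR the MS177-N1 comparison gave 2906 genes, a count that rests on a few libraries. The change with MS177-N1 went with exonic length across genes (Spearman rho = -0.43, and 0 once a length and GC trend was removed). After that removal 2426 genes passed, against 2807 of the same 10176 before, 1825 of them shared. Part of the calls thus depended on the trend. RNA of MS177-treated cells in these libraries would lower the FOXM1 and G2/M genes, and their median was -0.11 ± 0.06 (SE over genes) against -2.72 with MS177. The same DMSO libraries gave 19 of 10852 genes with MS177-N2 and 1 of 11748 with C24 (limma). These counts argue against handling of the DMSO libraries as the only source. Leaving out DMSO replicate 2 gave 215 genes and the fit of all libraries 5, so the size of the count is uncertain. Handling of the MS177-N1 libraries was not tested, and it stays open beside a response of this line.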

How the results depend on the processing

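The back-transformed scale, limma voom, the pseudocount of 0.5, the deposited values for comparisons between compounds and lines, and fits without the 3 doubted libraries were chosen after seeing the data. Counts for MS177 against DMSO in T47D-TR and against each other compound there stayed within 1.5 times of their values under every alternative. Over named genes, 5597 of 6516 alternative values kept direction and side of the threshold, 774 lost the call, 65 gained it, 79 changed direction without a call and 1 reversed. Over lists, 469 of 569 did, 88 lost the call, 7 gained it, 5 changed direction without a call and 0 reversed. The reversed value was GJA1 between T47D and T47D-TR, -0.443 with the deposited log2 values, a scale that compresses low counts. Of 77 list calls against DMSO, 0 held with an estimated correlation, a form with 2 degrees of freedom or fewer there that can lose calls of independent genes. Fry, which tests for a change in a shared direction, called 48 among all lists tested against DMSO and not only among those 77. Where no cause is given below, the cause was not tested. Fits without a library have fewer samples and fewer degrees of freedom, and where 1 library of a group remains the spread comes from the other groups.

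With all libraries of a line in 1 fit, counts against DMSO were 3150 (MS177 in T47D), 0 (MS177-N1 in T47D), 0 (C24 in T47D), 5 (MS177-N1 in T47D-TR), 0 (C24 in T47D-TR), 99 (MS177-N2 in BT-549) and 11 (MS8815). Without the mean trend they were 6 (MS177-N1 in T47D), 45 (C24 in T47D) and 0 (C24 in T47D-TR). Voom gave 45 (C24 in T47D), quantile scaling 5 and the back-transformed scale 11 (MS177-N1 in T47D), and the back-transformed scale 2 (C24 in T47D-TR). Without a filter MS8815 gave 434, and 328 genes moved the same way with MS177 and MS8815. In fits of the compared libraries alone, MS177 gave 44, 0 and 0 against MS177-N1, MS177-N2 and C24 in T47D and 3179 against MS177-N1 in BT-549, and MS8815 gave 28 against MS8815-N and 99 against EPZ-6438. For these last comparisons quantile scaling gave 66 and 44, the deposited values 0 and 0, and leaving out the 3 doubted libraries 6583 and 5122. Between T47D and T47D-TR a pseudocount of 0.5 gave 19 genes and the deposited values 0.

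Leaving out 1 library at a time gave, against DMSO, 48 to 12368 (MS177), 15 to 952 (MS177-N2) and 46 to 2390 (C24) in T47D. In T47D-TR it gave 4779 to 5808 (MS177), 215 to 2976 (MS177-N1), 11 to 43 (MS177-N2), 2 to 118 (C24), 138 to 6988 (MS8815), 0 to 7523 (MS8815-N) and 14 to 5050 (EPZ-6438). In BT-549 it gave 2445 to 4277 (MS177), 6 to 22 (MS177-N1), 121 to 1383 (MS177-N2) and 36 to 778 (C24). MS177 against MS177-N1, MS177-N2 and C24 gave 9315 to 12022, 80 to 12871 and 104 to 12998 in T47D, and 3252 to 4693, 3732 to 5445 and 3351 to 5002 in BT-549. MS8815 gave 0 to 7722 against MS8815-N and 0 to 0 against EPZ-6438. Between lines the counts were 0 to 5507 (T47D and T47D-TR), 0 to 7103 (T47D and BT-549) and 2522 to 3249 (T47D-TR and BT-549).

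Replicate numbers were not used as pairs, since over 11 comparisons the deviations from the group mean of libraries with the same number correlated from -0.725 to 0.734, above 0.1 in 3. With the number as a block, counts against DMSO were 916 (MS177), 21 (MS177-N2) and 296 (C24) in T47D, 54 (MS177-N2) and 23 (C24) in T47D-TR, and 2883 (MS177-N1, where the correlation was highest) and 145 (C24) in BT-549. The block gave 460, 986 and 1310 for MS177 against MS177-N1, MS177-N2 and C24 in T47D, 1910, 9509 and 9073 in BT-549, and 312 and 96 for MS8815 against its controls. Between lines the block gave 0, 0 and 1997.

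With 2 libraries per group a large spread between replicates hides changes, and depth is known for T47D and BT-549 alone, where genes with few reads carry wide error.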

Other observations

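The lists below had no camera call for MS177 against DMSO in the line named, and their counts were the same adjusted over the list alone. Of 11 PRC2 subunits tested in T47D-TR, 3 rose and 5 fell, with PHF1 up from 169 to 833 and the histone chaperone RBBP7 down from 2454 to 936 normalized counts. In BT-549, 0 of 13 passed. Luminal markers in T47D-TR rose in 10 and fell in 12 of 26 cases, with KRT7 up 10.1-fold. Apoptosis regulators there rose in 12 and fell in 6 of 26 cases, and hypoxia genes rose in 6 and fell in 15 of 30. Of 12 ubiquitin ligase subunits used by degraders, 4 rose and 3 fell in T47D-TR, and VHL alone rose in BT-549, from 7089 to 14560 normalized counts. Of the leukocyte markers 0 were tested in T47D-TR.

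The tests of the next pattern were chosen after the result was seen, apart from the removal of a length and GC trend. A set of 44 genes was lower with MS177-N2 than with MS177-N1 and C24 in T47D-TR, and RNA of MS177-treated cells does not explain it, since the FOXM1 and G2/M median was 0.03 ± 0.05 (SE over genes) against -2.59 with MS177. After the length and GC trend was removed, 36 of 43 still passed. Adding the counts of overlapping genes in T47D-TR left a median of 59% of the log2 change over 11 genes, above 50% in 8 of them, so reads moved to an overlapping gene stay open for part of the set. A response that MS177-N2 shares with MS177 may be a candidate explanation. With MS177 in BT-549, 37 of the 39 measured were lower than in DMSO, against 50.3% of all 16345 genes, but the overlap had been seen before this count was taken, so it is no test and the explanation stays open.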
